A study of Mus musculus with 2 samples.

How the data were processed

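Chromatin accessibility was measured by DNase-seq in kidney tissue of male B6CASTF1/J mice aged 2 months. B6CASTF1/J animals are the first-generation offspring of a C57BL/6 laboratory mouse and a CAST mouse, a strain derived from wild mice. In DNase-seq, nuclei are cut lightly with DNase I, an endonuclease, and the cut ends are sequenced. Stretches where cuts pile up are DNase I hypersensitive sites, called peaks here. Short protected stretches within them are called footprints. The labels give 1 group, kidney, with 2 biological replicates, so no comparison between groups exists. Values are given per replicate or as mean ± SD (n = 2), and the spread between the replicates is the only error between samples. Per the labels the replicates have separate biosamples and animal numbers but the same donor identifier, so whether this spread is one between animals is not certain.

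For each replicate the authors deposited 2 peak lists, a footprint list and a track of false discovery rates, all on mouse build mm10 per the labels. Per the file lists that come with the samples, each peak list was made from the alignment of its own sample, so peaks were called per sample and not on pooled samples. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. The peak height is a signal value that the authors deposited for each peak, and the labels do not state its normalization. All heights (100%) were whole multiples of 1 step per library, within 0.1 step. If 1 step is 1 cut in RPM, which no label states, the libraries held 337 M and 185 M reads (M, mega). The FDR (q-value) track deposited by the authors lists only intervals under 0.05. The lowest FDR under any peak was below 0.001 in one list of each replicate and below 0.05 in the other, and the lists are named here by these thresholds. The FDR 0.001 lists were used throughout unless stated. The FDR that the authors deposited with the footprints was 0.01 for every footprint. Sequence differences between the CAST alleles and the reference were not measured.

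The reference was GRCm38 with the GENCODE M21 annotation. Every peak of the 4 lists lay inside its GRCm38 chromosome. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. Peaks were shared when they overlapped a peak of the other replicate by at least 1 bp. Chance overlap came from 10 shuffles of the other list within chromosomes, or within the FDR intervals for footprints. Correlations of log2 height were taken across peaks paired between replicates, and peaks are not independent replicates. Peaks were assigned in the order promoter (within 500 bp of the TSS, the transcription start site, of a protein-coding transcript), exon, intron and intergenic. A gene's promoter was open when a peak overlapped 500 bp on either side of any of its protein-coding TSSs. Distal peaks lay over 1 kb from any protein-coding TSS and within 50 kb of a TSS of the gene. Shares from a single replicate have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only.

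Each of 24 gene lists was compared with 10000 random lists of protein-coding genes of the same size, matched on the decile of promoter CpG content (observed over expected). A list was called above when it lay at or over percentile 99 in both replicates, and below when it lay at or under percentile 1 in both. The lists covered kidney cell types, sex-biased kidney genes, kidney transcription factors, nephron progenitors, housekeeping genes, Hox genes, chemosensory receptors and markers of other tissues. Kap and Slc7a13 stand in both the proximal tubule and the male-biased list, Gata3 and Tfcp2l1 in both the principal cell and the transcription factor list, and Foxi1 in both the intercalated cell and the transcription factor list. For each list the rule for naming genes took the 3 members with the highest mean promoter peak and up to 3 members without a promoter peak in either replicate. It added the 10 genes with most shared distal peaks, the 10 strongest shared distal peaks and the 5 peaks each way that differed most between replicates among peaks with a mean height above the median. Some genes that the rule takes are not used here. Gene lists, motifs, the percentile thresholds and these rules were fixed before the data were examined, while the 2-fold and 1.5-fold thresholds for counting motifs were not.

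For 28 transcription factor motifs, consensus matches on either strand were counted in 150 bp around each peak's midpoint. The plan named the summit, and the midpoint replaced it after the summit column was found to hold the value 75 for every peak. The share of peaks with a match was divided by that in windows of the same chromosome outside peaks and FDR intervals, matched on GC content in 2% bins. A match inside peaks counted as footprinted when it overlapped a footprint by 1 bp, beside the same share for the consensus written backwards without complementing it. SP/KLF was left out there because its consensus reads the same backwards, which left 27 motifs. A sequence was said to have several copies when at least 3 of 5 words of 32 bases from it occurred more than 1 time in the genome. On simulated data, a planted overlap of 70.16% was recovered, 100 of 100 lists of 20 open genes were called above, 2 of 100 random lists were called, and 0 planted motif matches were missed. Smaller lists and lists chosen for CpG-rich promoters were not simulated.

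Alternatives changed 1 choice at a time: the FDR 0.05 lists, the strongest 50% of peaks by height, equal numbers of peaks, a 50% reciprocal overlap, promoter half-widths of 100, 1000 and 2000 bp, windows of 20 and 100 kb, unmatched random lists, other motif windows and each replicate alone. Motif windows without repeats and windows around the TSS at the 5' end of the gene only were chosen after seeing the data. Cuts per base were not used here, so cleavage profiles at motifs were not computed.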

Results

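The data were DNase-seq peaks, footprints and false discovery rates from kidney tissue of male B6CASTF1/J mice, with 1 library for each of 2 biological replicates. The labels give the replicates separate biosamples and animal numbers but the same donor identifier, so it is not certain that an SD here is a spread between animals. Replicate 1 held 172858 peaks at FDR 0.001 and replicate 2 held 171493 (mean 172176 ± 965, SD, n = 2). Median widths were 200 and 177 bp, and the peaks covered 1.20% ± 0.132 (SD, n = 2) of the genome. The median peak height was 0.627 in replicate 1 and 1.12 in replicate 2. In peaks paired between the replicates, replicate 2 was higher by a median of 1.82-fold. The height step also differed, at 0.00297 in replicate 1 and 0.00541 in replicate 2. Counted in steps, the median heights were 211 and 208, so the shift lies in the height unit and is not read as more open chromatin. This general shift enters every SD of a height given here. A small SD, as at Umod below, is therefore not agreement relative to other peaks.

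The strongest open sites of the kidney recurred in both replicates, while the weakest recurred in fewer than 50%. Of the replicate 1 peaks, 82.2% (95% interval 82.0 to 82.3) overlapped a replicate 2 peak, and 83.4% (83.2 to 83.6) did so the other way. Shuffled lists overlapped at 2.57%. The share rose from 43.1% and 47.3% in the lowest decile of height to 99.9% and 99.03% in the highest. When the other replicate's FDR 0.05 list was used, 92.1% of replicate 1 peaks and 91.7% of replicate 2 peaks found a partner.

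**Figure D1:**
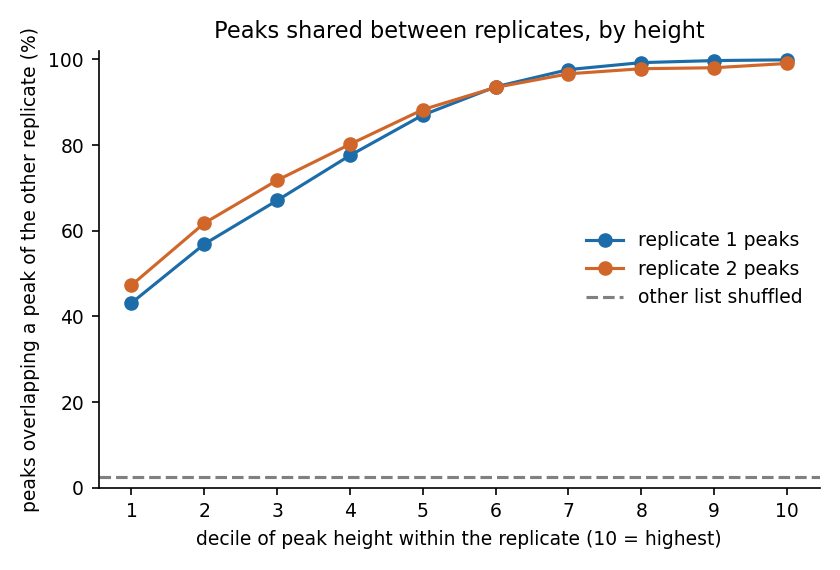
Share of each replicate's peaks (%) that overlap a peak of the other replicate, by decile of peak height within the replicate (10 is the highest). Blue and orange points are replicates 1 and 2, the dashed line is the mean over shuffled lists (2.57%), and the share rises from 43.1% and 47.3% in decile 1 to 99.9% and 99.03% in decile 10.

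Heights of kidney sites were correlated between the replicates, at promoters and away from them. Across the 141130 paired peaks, log2 heights had a Pearson r of 0.93 (interval 0.93 to 0.94 from resampled blocks of 1 Mb) and a Spearman rho of 0.91. Within 1 kb of a TSS r was 0.98 and replicate 2 was higher by a median of 1.98-fold. At distal peaks r was 0.90 and the median was 1.77-fold. After centring, 93.2% of all pairs lay within 2-fold, and the SD of the log2 ratio was 0.55. If 1 step of height is 1 cut, counting noise alone would give an SD of 0.15. A chi-square test of the 2 libraries' heights in steps gave 24.7 per degree of freedom. On that reading, the libraries differed by more than counting noise.

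Kidney open chromatin was concentrated at promoters. Promoter windows held 14.7% ± 0.935 (SD, n = 2) of peaks, which is 11.6-fold ± 0.739 their share of the genome. Exons held 7.25% ± 0.0542 of peaks, 2.34-fold their genome share. Introns held 39.5% ± 0.305 and intergenic sequence 38.5% ± 0.576, which are 1.16-fold and 0.626-fold their shares. A peak went to the first class it touched by 1 bp, while genome shares count single bases. Randomly placed peaks would thus also exceed 1 for promoters and exons and fall below 1 for intergenic sequence. These ratios overstate the difference from random placement, and no shuffled level was computed for them. Promoter peaks were also the highest, with median heights of 1.93 and 3.50 in replicates 1 and 2, against 0.544 and 0.946 for intergenic peaks. Of 21853 protein-coding genes, 14589 and 14778 had an open promoter, 14347 of them in both replicates. Open promoters made up 11.6% of the genes in the lowest decile of promoter CpG in each replicate, and 97.5% and 97.8% in the highest.

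Promoters of genes that mark most tubule segments and the vessels were open in nearly every case. Of the 26 proximal tubule genes, 25 were open in each replicate, where random lists averaged 48.6% and 49.2%. The exceptions were Slc22a8, an organic anion transporter, with no promoter peak in replicate 1, and Slc7a13, an amino acid transporter, with none in replicate 2, both named after their values were seen. The highest promoter peaks of the list were at Pck1, a gluconeogenic enzyme (chromosome 2, 173153048 to 173159273, height 8.65 ± 2.46), Ggt1, a brush-border glutathione enzyme (8.36 ± 2.78), and Dab2, an adaptor of endocytosis (6.96 ± 2.49). All 13 genes of the distal convoluted and connecting tubule were open in both replicates, with the highest peaks at the magnesium-handling gene Cnnm2 (32.4 ± 14.3) and the kinases Wnk1 (14.5 ± 4.39) and Wnk4 (8.56 ± 6.04). All 13 principal cell genes were open as well, led by the transcription factor gene Tfcp2l1 (6.18 ± 2.26), the sodium channel subunit gene Scnn1g (5.74 ± 2.88) and Gata2 (4.64 ± 2.29).

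In the thick ascending limb list, 10 of 11 promoters were open in each replicate. They included Egf, a growth factor made in the kidney (9.72 ± 5.33), and Umod, which encodes uromodulin (chromosome 7, 119462711 to 119479282, 5.16 ± 0.0983). Cldn19, a tight junction gene, had no promoter peak. All 12 endothelial genes were open, with the highest peaks at Ehd3 (7.87 ± 2.92), the VEGF receptor gene Flt1 (4.31 ± 2.42) and Egfl7 (4.31 ± 1.79). In the stroma and mural list 11 of 12 were open, led by Cspg4 (4.90 ± 3.02), which has another gene's TSS within 1 kb, and Pdgfra (3.46 ± 2.33), while the renin gene Ren1 had no promoter peak. These 6 lists lay above percentile 99 of random lists in both replicates.

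Of the 8 male-biased kidney genes, 8 and 7 were open in replicates 1 and 2, which was also above random lists (percentiles 99.98 and 99.58). Odc1, the ornithine decarboxylase of polyamine synthesis, had the highest peak (chromosome 12, 17544794 to 17551505, 14.4 ± 5.39), followed by Cyp4b1 (8.20 ± 5.72) and Cyp2e1 (4.92 ± 1.39). Of the 5 female-biased genes, 5 and 4 were open, among them the transporter gene Slc22a7 (2.83 ± 0.335), the prolactin receptor gene Prlr (2.81 ± 1.08) and Abcc3 (1.48 ± 0.828). This list passed in replicate 1 and missed in replicate 2 (percentile 97.96). So did the intercalated cell list, with 9 and 8 of 11 open (percentile 98.82 in replicate 2), and the kidney epithelial transcription factors, with 23 and 22 of 23 open (percentile 98.80). Intercalated cell promoters were low, the highest at Oxgr1 (1.46 ± 0.419), Atp6v1b1, a proton pump subunit gene (1.35 ± 0.482), and Hmx2 (1.11 ± 0.494), and Aqp6 and Slc4a1 had none. Among the transcription factors, Nr3c2, the mineralocorticoid receptor gene, was highest (chromosome 8, 76899442 to 77245012, 19.7 ± 9.64), then Pou3f3 (8.70 ± 1.62) and Irx3 (7.41 ± 3.09).

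Other lists stood within the range of random ones. Podocyte promoters were open in 10 of 13 genes in each replicate, among them Cdkn1c (5.90 ± 2.18) and Dach1 (5.01 ± 2.29), with no promoter peak at the chloride channel gene Clic3 or at the nephrin gene Nphs1. Nephron progenitor genes had 6 of 7 open, at low heights for Osr1 (1.79 ± 1.38), Cited1 (0.752 ± 0.274) and Meox1 (0.582 ± 0.273), and the growth factor gene Gdnf had none. Immune genes had 6 and 4 of 13 open, including Cd74 (1.39 ± 0.186), Cd68 (0.756 ± 0.254) and Spi1 (0.519 ± 0.183), and not C1qa or Cd3e. All 14 housekeeping promoters were open (percentiles 97.55 and 97.03), with Rplp0 (20.5 and 29.5 in replicates 1 and 2), Rpl13a (22.2 ± 8.31) and Ywhaz (20.6 ± 11.4) highest. With every promoter open this list could go no higher, so a call above against matched lists was out of reach. For podocyte and nephron progenitor genes percentile 99 of random lists was 100% open, which left a call above little room.

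Promoters of liver, skeletal muscle, erythroid and adrenal cortex markers were mostly closed. Hepatocyte genes had 3 and 1 of 11 open, where random lists averaged 34.2% and 34.5%. The highest of them, Ahsg, reached only 0.250 ± 0.0433, the albumin gene Alb had a peak in replicate 1 alone (0.247), and Apoa2, Cps1 and Cyp2c29 had none. Skeletal muscle genes had 2 of 11 open in each replicate (random 41.5% and 42.1%), with Actn3, which has another gene's TSS within 1 kb, highest (0.485 ± 0.0557) and none at Ckm, Mb or Myh1. Erythroid genes had 2 of 9 open (random 34.0% and 34.5%), among them the erythropoietin receptor gene Epor (1.65 ± 0.866). Adrenal cortex genes had 1 of 8 (random 28.3% in both), the cholesterol transporter gene Star (0.956 ± 0.314). Neuronal genes had 6 of 13 open in each replicate (random 69.2% and 70.2%). The open ones included the glutamate receptor gene Grin1 (1.53 ± 1.24) and Slc17a7 (0.930 ± 0.542), while Gad1, Neurod1 and Neurod6 had no promoter peak. Adipocyte genes had 4 and 5 of 9, led by the lipase gene Lipe (8.75 ± 6.41), Plin1 (1.59 ± 0.929) and Pparg (1.12 ± 0.520), without Adipoq, Cfd or Cidec. None of these 6 lists was called against matched random lists, and the neuronal one came nearest to a call below (percentiles 1.70 and 1.11). For erythroid and adrenal cortex genes percentile 1 of the matched random lists was 0% open, which left a call below little room. Against unmatched ones the hepatocyte, skeletal muscle, erythroid and adrenal cortex lists were called below, as were the neuronal and skeletal muscle lists with the strongest 50% of peaks.

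Germ line, posterior Hox and chemosensory receptor promoters were open less often than random lists in both replicates. Germ line and pluripotency genes had 2 of 8 open (percentiles 0.58 and 0.40), the RNA-binding protein gene Dazl (6.29 ± 3.59) and the meiotic gene Sycp3 (1.40 ± 0.563), while Ddx4, Nanog and Pou5f1 had none. Hox genes of groups 12 and 13 had 2 of 6 open, Hoxc13 (1.12 ± 0.451) and Hoxd13 (0.518 ± 0.0395), where random lists averaged 91.7% and 92.7%. Hox genes of groups 1 to 11, by contrast, had 29 and 28 of 33 open, with Hoxc10 (11.4 ± 7.48), Hoxa7 (10.8 ± 5.35) and Hoxa10 (10.4 ± 5.36) highest and none at Hoxa2, Hoxb1 or Hoxc6. Of 1463 chemosensory receptor genes, 33 and 30 were open, against 18.9% and 18.8% in random lists. Their highest peak, at Vmn1r4 (11.2 ± 3.24), lay within 1 kb of another gene's TSS, and Olfr433 (1.65 ± 1.33) and Olfr1441 (1.57 ± 0.846) came next.

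The calls for the proximal tubule, endothelium and chemosensory lists held under all 6 other settings. Among these, the settings with each replicate alone could not end a call, since a call already needs both replicates. With unmatched random lists the male-biased, thick ascending limb, stroma, germ line and Hox 12 and 13 calls ended. With the strongest 50% of peaks the male-biased, thick ascending limb, distal convoluted, principal cell, stroma and germ line calls ended. The germ line call also ended at half-widths of 100 and 2000 bp, that of distal convoluted tubule at 100 bp and that of Hox 12 and 13 at 2000 bp. Calls were also gained: the kidney transcription factors above with unmatched lists and at 100 and 2000 bp, the housekeeping genes above with unmatched lists and with the strongest 50% of peaks, and the nephron progenitors below with the latter.

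**Figure D2:**
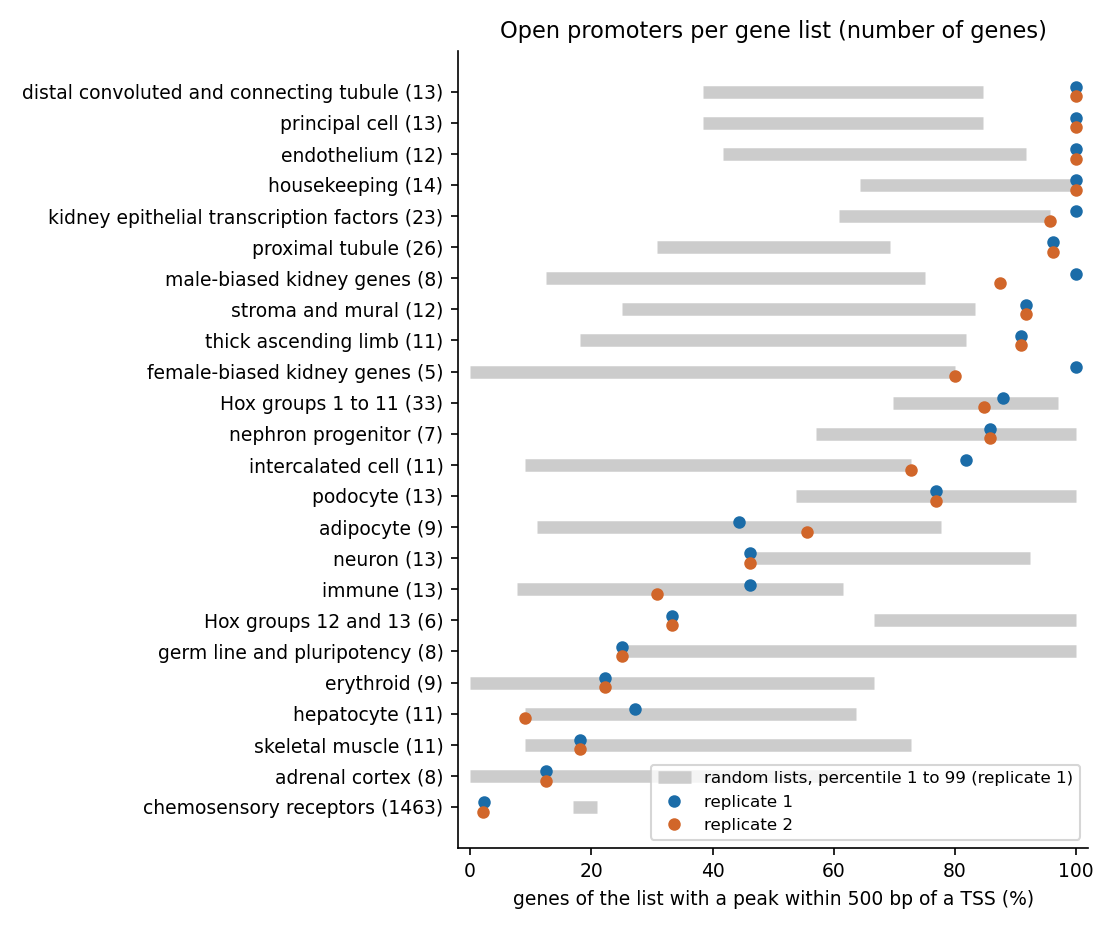
Share of the genes of each list (%, number of genes in brackets) with a peak within 500 bp of a TSS, in replicate 1 (blue) and replicate 2 (orange). Grey bars span percentiles 1 to 99 of the 10000 random lists in replicate 1. The proximal tubule, thick ascending limb, distal convoluted and connecting tubule, principal cell, endothelium, stroma and mural, and male-biased lists lie to the right of the bars in both replicates, and Hox groups 12 and 13 and the chemosensory receptors to the left.

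Distal open sites were dense around proximal tubule genes and around Hox genes of groups 1 to 11. A proximal tubule gene had a median of 18.5 and 15.5 distal peaks within 50 kb in replicates 1 and 2, where random lists averaged 7.07 and 7.01. Fbp1, a gluconeogenic enzyme gene, had 44 and 22, the urate transporter gene Slc22a12 had 42 and 26, and Pck1 had 35 and 19. Fbp1 and Slc22a12 were chosen after their values were seen. Windows of 100 kb around Fbp1, Pck1 and Hoxa5 to Hoxa13 held 28, 15 and 31 peaks called in replicate 1 that had no partner in replicate 2. Hox genes of groups 1 to 11 had medians of 32 and 23 (random 9.05 and 9.08), but they lie in clusters whose windows share peaks. Endothelial genes, at 14.5 in each replicate (random 8.24 and 8.21), and kidney epithelial transcription factors, at 17 and 14 (random 8.91 and 8.92), also lay above random lists. Chemosensory receptor genes, at 0 in each replicate, lay below. No other list was called, among them the thick ascending limb (13 and 13, percentiles 98.08 and 98.16) and podocytes (14 and 14, percentiles 98.14 and 98.05), and Hox groups 12 and 13 (21 and 16.5) missed in replicate 2 (percentile 97.41). The proximal tubule and Hox 1 to 11 calls held under all 7 other settings, where those with each replicate alone again could not end a call. Only these 2 calls held with the strongest 50% of peaks. The endothelial and transcription factor calls also ended at 100 kb and with the TSS at the 5' end alone, an alternative chosen after seeing the data, and the chemosensory call ended at 20 kb. Calls were gained above for adipocyte genes at 20 kb and for housekeeping genes and Hox 12 and 13 with the TSS at the 5' end alone, and below for nephron progenitors at 100 kb.

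Individual genes differed widely in distal peaks, and some differed between the replicates. Pou3f3, a POU-domain transcription factor gene of the nephron (chromosome 1, 42695768 to 42703176), had 54 distal peaks in replicate 1 and 8 in replicate 2. In the whole window of 50 kb around it, from 42645768 to 42753176, 59 peaks were called in replicate 1 and 11 in replicate 2, or 61 and 20 at FDR 0.05. Most shared distal peaks were found around Tns1, a focal adhesion gene (72 shared, 118 and 83 per replicate), Pde4d, a cyclic AMP phosphodiesterase gene (66), Trio (63) and Rere (62). Gse1, Ank3, Agap1, Casz1 and Itpr1 were also among the 10 genes with most, with 57, 55, 54, 48 and 48. Windows were drawn around every TSS of a gene, and their widths were not compared.

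**Figure D3:**
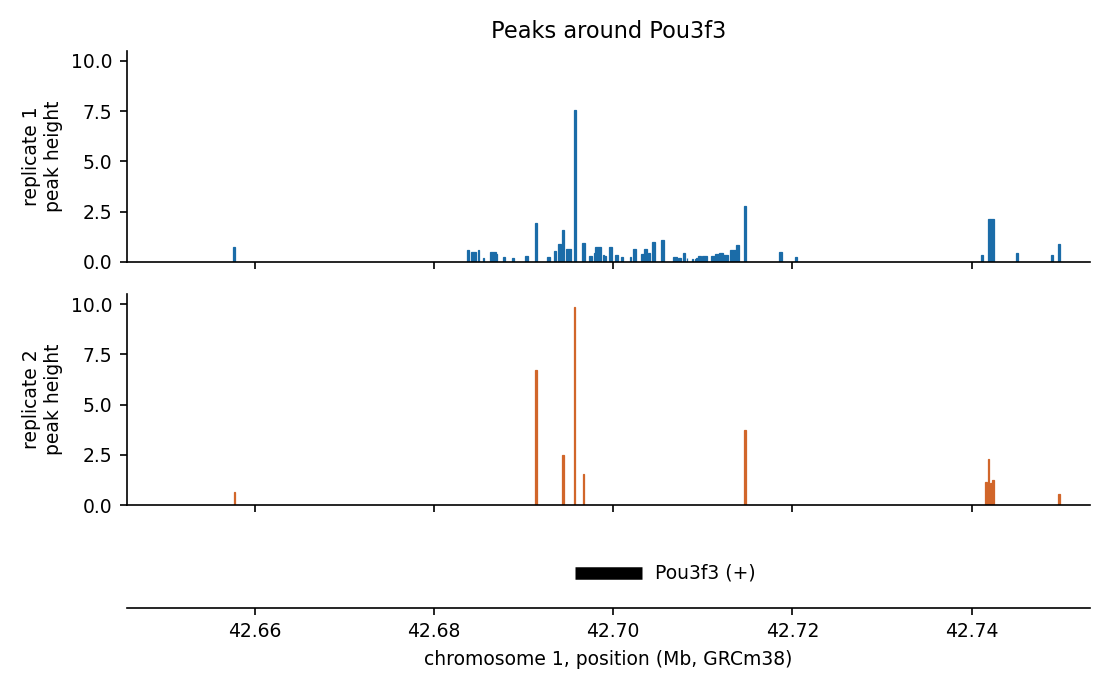
Peaks at FDR 0.001 around Pou3f3 on chromosome 1 (GRCm38 position in Mb), with bar height the authors' peak height in replicate 1 (blue, 59 peaks) and replicate 2 (orange, 11 peaks). The black bar is the gene. The tallest peak, at the promoter, is present in both, while a series of low peaks upstream of, along and downstream of the gene is called in replicate 1 alone.

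The strongest shared distal sites lay both between genes and in introns. The highest was on chromosome X at 169998241 to 169998400, in an intron of Mid1, with heights of 24.3 and 101, but its sequence has several copies in the genome, as does that of its neighbour at 169997961 to 169998060 (26.2 and 41.6). The next was intergenic, on chromosome 16 at 4541861 to 4542060, 11.002 kb from the TSS of Tfap4 (29.0 and 58.9). Others lay on chromosome 5 at 25529581 to 25529880 (34.6 ± 15.6), on chromosome 7 at 127477941 to 127478160, 1.15 kb from Fbrs (32.9 ± 13.8), and on chromosome 8 at 126666541 to 126666660, 72.6 kb from Irf2bp2 (32.4 ± 17.4). An intron of Nr1d1, a nuclear receptor gene of the circadian clock, held one on chromosome 11 at 98773821 to 98774200 (30.6 ± 11.4). The highest of the others was intergenic, on chromosome X at 143482981 to 143483140, 35.5 kb from Pak3 (33.8 ± 7.43).

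Among stronger peaks, a few differed between the replicates by far more than the general shift. On the centred log2 scale (replicate 2 over replicate 1), the peak on chromosome 13 at 44445661 to 44445828, 284 kb from Jarid2, stood at -3.04 (heights 2.54 and 0.562). An intronic peak of Nr1h4, the bile acid receptor gene, on chromosome 10 at 89465160 to 89465268, stood at -2.68, and one of Hivep1 at -2.73. In the other direction, a peak 4.45 kb from Diras2, on chromosome 13 at 52535661 to 52535800, stood at 1.92 (heights 0.493 and 3.40), and an intronic peak of Ccdc65 at 1.82. A peak at Gm10722, at -2.76, lies in sequence with several copies.

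Motifs of the tubule regulator HNF1 and of the insulator protein CTCF had the 2 highest ratios in kidney peaks, and against GC-matched windows that of HNF4, another tubule regulator, came next. HNF1 matches were found in 0.611% ± 0.113 (SD, n = 2) of peaks, 49.7-fold ± 1.19 their share in GC-matched windows, of which only 23 and 18 held a match. CTCF matches were found in 7.02% ± 0.935 of peaks (14.9-fold ± 2.23) and HNF4 matches in 2.37% ± 0.0745 (8.68-fold ± 0.0406). Motifs typical of promoters followed, with NRF1 at 7.54-fold ± 0.978, ETS at 5.65-fold ± 0.112 and the USF/MITF E-box at 5.57-fold ± 0.207. REST, a repressor of neuronal genes, stood at 4.53-fold ± 0.318, and the PPAR/RXR motif DR1, bound by regulators of fatty acid use, at 3.45-fold ± 0.365. MEF2 stood at 3.31-fold ± 0.0301, PU.1 at 2.52-fold ± 0.0489, and the glucocorticoid/androgen receptor motif at 2.16-fold ± 0.122. Relative to the median paired peak, peaks with a CTCF match were 1.42-fold as high in replicate 2 as in replicate 1, those with a REST match 1.76-fold and those with an HNF1 match 0.734-fold.

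Other epithelial motifs were enriched less. AP-1 reached 1.89-fold ± 0.0416, FOX 1.63-fold ± 0.0279, ESRR 1.62-fold ± 0.128 and GRHL/TFCP2 1.53-fold ± 0.0117, and GATA lay below the background at 0.823-fold ± 0.0134. In total 13 of the 28 motifs were at least 2-fold enriched in both replicates, a threshold chosen after seeing the data. With flanking windows of the same peaks as background, the order changed: CTCF stood highest at 9.93-fold ± 0.991, then HNF1 at 6.86-fold ± 0.903, REST at 5.55-fold ± 1.03, HNF4 at 5.16-fold ± 0.293 and NRF1 at 4.78-fold ± 0.155. Much further down, below other motifs such as ETS and DR1, MEF2 stood at 1.34-fold ± 0.167 and FOX at 1.08-fold ± 0.0920. HNF1 also stood at 30.3-fold ± 2.51 over whole peaks and 78.3-fold ± 12.3 in windows without repeats, an alternative chosen after seeing the data. NRF1 had a higher mean than HNF4 in both of these settings, within the SD over whole peaks, at 7.20-fold ± 2.02 against 6.98-fold ± 0.649 over whole peaks and 7.36-fold ± 0.200 against 6.87-fold ± 0.281 without repeats. YY1 changed side, from 0.367-fold ± 0.000145 to 1.80-fold ± 0.173 with flanks and 1.63-fold ± 0.0928 in windows without repeats, as did ZEB/SNAI (0.790 to 1.12 with flanks) and NEUROD (1.06 to 0.918 without repeats). The mean of POU went from 1.34 to 0.995 ± 0.0909 with flanks, with replicates 1 and 2 at 1.06 and 0.931, so it cannot be told from 1.

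**Figure D4:**
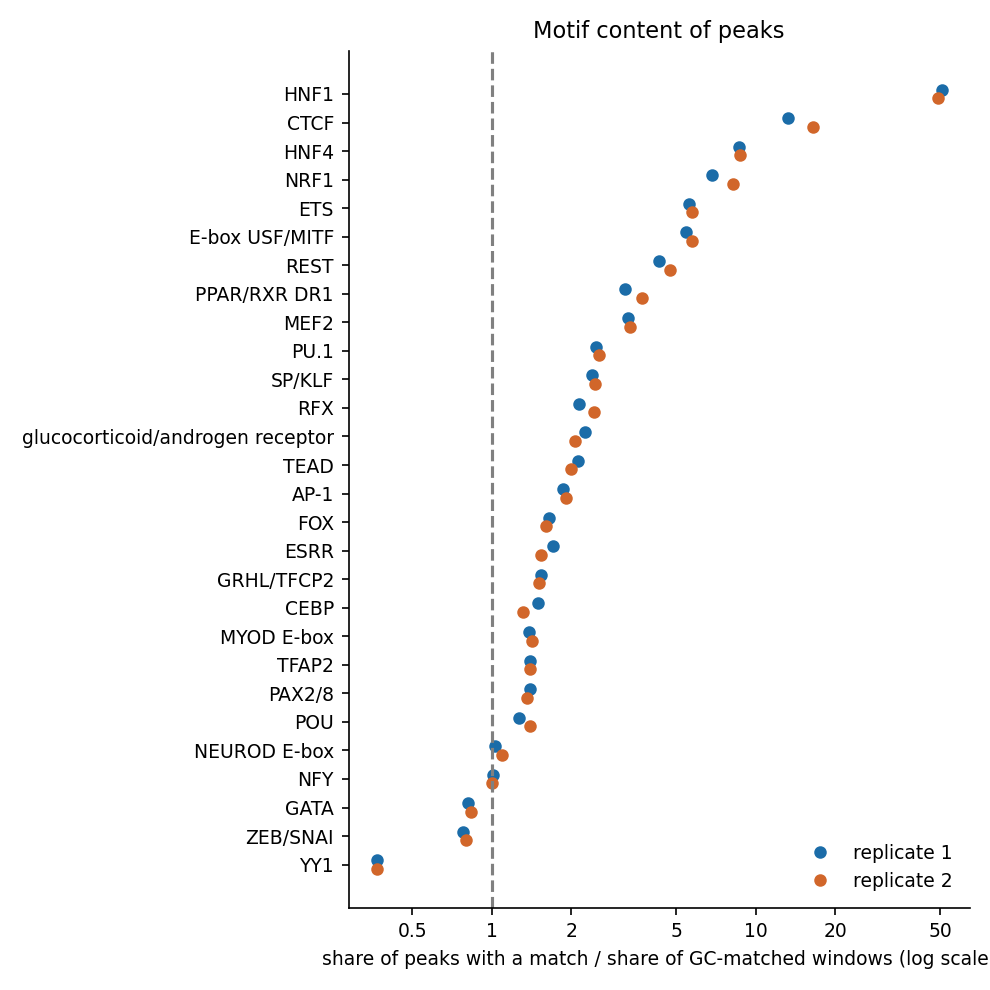
Share of peaks with a consensus match divided by the share of GC-matched windows, on a log scale, for 28 motifs in replicate 1 (blue) and replicate 2 (orange). The dashed line marks a ratio of 1. HNF1 (49.7), CTCF (14.9) and HNF4 (8.68) have the highest mean ratios.

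Among the motifs tested, matches of CTCF and NRF1 in peaks were the most often footprinted. The authors called 718353 footprints in replicate 1 and 592927 in replicate 2, with median widths of 10 and 12 bp, and 71.6% and 76.5% of them lay in peaks. At least 1 footprint was found in 91.7% and 90.2% of peaks. Of the replicate 1 footprints 51.3% overlapped one of replicate 2, and 60.8% did so the other way, against 17.7% and 19.3% for footprints shuffled within FDR intervals. Within shared peaks these shares were 68.9% and 69.8%.

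CTCF matches in peaks were footprinted in 95.2% ± 0.162 (SD, n = 2) of cases, against 39.2% ± 5.24 for the reversed consensus. NRF1 reached 93.9% ± 1.65, HNF1 84.2% ± 6.88 against 49.0% ± 11.4, and the USF/MITF E-box 79.7% ± 0.754 against 28.04% ± 2.27. HNF4 had the largest ratio to its reversed consensus, 3.01 ± 0.343, with 65.7% ± 3.51 of matches footprinted. DR1 (70.3% ± 0.250 against 34.8% ± 0.134) and ETS (66.8% ± 2.03 against 32.6% ± 0.953) were also footprinted about 2 times as often. So was the NEUROD E-box (ratio 2.01 ± 0.184), although its enrichment in peaks was only 1.06-fold. Its consensus can lie inside that of CTCF, so such a ratio need not reflect the factor named. FOX (15.1% ± 1.80 against 23.5% ± 1.71), GRHL/TFCP2 (19.8% ± 2.36 against 31.2% ± 2.02) and GATA (17.4% ± 2.01 against 19.6% ± 1.67) lay below their reversed consensus. The reversed GRHL/TFCP2 consensus can match the same sequences as that of CEBP, another of the motifs (32.4% ± 0.827 footprinted), so it is not a neutral control. In all, 12 of 27 motifs had a ratio of at least 1.5 in both replicates, a threshold chosen after seeing the data. With matches required to lie wholly inside footprints widened by 5 bp, the ratio was 4.52 ± 0.704 for HNF4 and 3.79 ± 0.0204 for DR1. Reversed matches were few for NRF1 (22 and 21), REST (50 and 42) and CTCF (79 and 70).

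**Figure D5:**
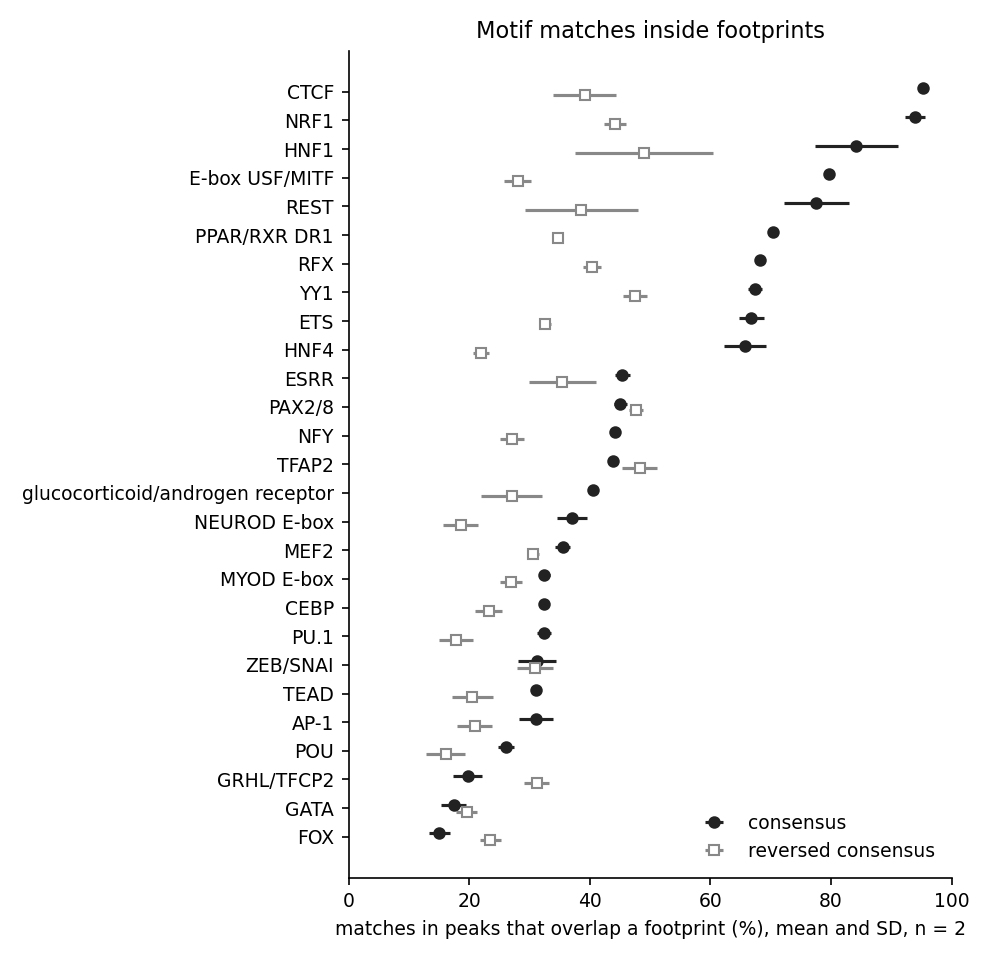
Share of consensus matches in peaks that overlap a footprint (%, filled circles) and of matches of the reversed consensus (open squares), as mean and SD over the 2 replicates, for 27 motifs. CTCF (95.2%) and NRF1 (93.9%) lie highest, and FOX and GRHL/TFCP2 lie below their reversed consensus.

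The X chromosome, present as 1 copy in males, had fewer and lower peaks than the autosomes. It held 26.4 and 24.8 peaks per Mb, against 70.3 and 69.9 on the autosomes, a ratio of 0.365 ± 0.0148 (SD, n = 2). The sparsest autosome, chromosome 3, held 56.5 and 55.2 per Mb. The median height of X peaks was 0.594 ± 0.0213 of that of autosomal peaks. The Y chromosome held 63 and 35 peaks.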

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

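The overlap reported in this part was not in the plan made before the data were examined. It concerns stretches of the FDR track that lie under 0.05 but hold no called peak. They enter the comparisons above only as sequence kept out of the motif background and as room for shuffled footprints. Replicate 1 had 123112 such stretches, with a median width of 4 bp, and replicate 2 had 58020, with a median of 5 bp. Of those in replicate 1, 0.972% overlapped such a stretch of replicate 2, against 0.0401% when shuffled. Of those in replicate 2, 1.94% overlapped one of replicate 1, against 0.0803% when shuffled. More of them overlapped any stretch under 0.05 of the other replicate, 20.5% of those in replicate 1 and 54.4% of those in replicate 2, and 9.96% and 20.1% overlapped its FDR 0.05 peaks, shares without a shuffled level here. They were singled out because the recurrence of peakless stretches, outside the peak lists, lies above its shuffled level. No explanation was tested.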

How the results depend on the processing

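Windows without repeats, distal windows around the TSS at the 5' end, and the counts of motifs past 2-fold and 1.5-fold were chosen after seeing the data; the other settings were planned. For peak number and width and for peak overlap between replicates, the strongest 50% of peaks by height numbered 86183.5 on average and overlapped at 86.8%, and they left 2 called lists for distal peaks instead of 5, with fewer peaks tested by construction. Peaks overlapped at 74.6% under the 50% reciprocal rule and at 79.5% with the FDR 0.05 lists, and footprints at 40.7% under the 50% rule, which is stricter by construction. Distal peaks alone gave a correlation of heights of 0.90 and an X to autosome density ratio of 0.347. A promoter half-width of 1000 bp gave shares of 18.8% promoter, 6.34% exon, 37.3% intron and 37.6% intergenic, since wider promoters take peaks from the other classes. With flanking windows as background, POU went to 0.995 (with the replicates on either side of 1), ZEB/SNAI to 1.12 and YY1 to 1.80. In windows without repeats, YY1 went to 1.63 and NEUROD to 0.918, and the cause was not tested for these 5 motif values. With replicate 2 alone 10 lists were called for open promoters and with replicate 1 alone 13, where the female-biased, intercalated cell and kidney transcription factor lists joined. For distal peaks the counts were 5 and 7, the latter with nephron progenitors below and Hox groups 12 and 13 above. Beyond the spread between replicates moved 76 of 144 values per list for open promoters, 81 of 168 for distal peaks, 62 of 140 motif ratios in peaks besides the 5 whose mean changed side, 15 of 81 in footprints and 45 of 585 values of named genes. These totals include the values of each replicate alone, which by construction cannot move beyond that spread, so they understate the share that moved. In footprints the 15 came from 1 alternative for each of the 27 motifs. Cuts counted per peak, cleavage at motifs and other flanks for it were not run because per-base cuts were not used here. A stricter footprint threshold was not run because every footprint carries the same FDR. Overlap and correlation need both replicates and have no value without either. No paired analysis was possible because there is 1 group. Depth is known only by inference, and its effect on which weak peaks are shared was not settled.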

Other observations

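All tests in this part were planned before their results were seen, except the comparison of X and autosomal peaks at matched heights and the matching of ETS, NRF1 and HNF4 peaks. The patterns themselves were noticed in the data, and no difference between biological groups was tested, because the design has 1 group; the share of proximal tubule cells and the copy number of the X were tested within it.

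Peaks near different gene lists shifted differently between the replicates, in values not matched on promoter distance, GC content or height. Relative to the median paired peak, peaks near the male-biased kidney genes were lower in replicate 2, with a median log2 ratio of -0.37 (interval over genes -0.46 to -0.20) and 8 of 8 genes below 0. Peaks near Hox groups 12 and 13 stood at -0.07 (interval -0.09 to -0.0025), and those near the female-biased genes at -0.33, with 4 of 5 genes below 0 and an interval from -0.57 that ends at 0. Neighbours such as Hoxc12 and Hoxc13 share peaks but were resampled as separate genes. The Hox interval may thus be too narrow to set it apart from 0. Peaks near the neuronal (0.21), skeletal muscle (0.26), podocyte (0.11), housekeeping (0.11) and erythroid (0.10) genes stood above 0 with their intervals, and those near the germ line genes stood at 0.19 with an interval that starts at 0. Neighbouring globin genes of the erythroid list may share peaks too. Before centring, the median log2 ratio was 0.984 within 1 kb of a TSS, against 0.864 for all pairs. By quartile of height it ran from 0.639 in the lowest to 1.03 in the highest. Such general shifts with promoter distance and height were not separated from the differences between lists.

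On the same scale, peaks also differed by motif: those with a REST match stood at 0.82 (1.76-fold higher in replicate 2, 571 pairs) and those with a CTCF match at 0.51 (1.42-fold, 10410 pairs), while HNF1 peaks stood at -0.45 (773 pairs). The difference from other peaks was 0.55 for CTCF and -0.45 for HNF1 unmatched, 0.66 and -0.25 matched on GC content, 0.52 and -0.46 matched on height, and 0.40 and -0.45 matched on width, which argues against any of these 3 as the whole cause for these motifs. GC matching took most of the smaller differences of ETS (0.19 to 0.03), NRF1 (0.19 to 0.04) and HNF4 (-0.12 to -0.01), and height matching did so for ETS (0.04) and NRF1 (0.07), so GC content and height stay open for those. A smaller share of proximal tubule cells in replicate 2 would lower the peaks near proximal tubule genes. Paired peaks near these genes stood at 0.0067 (interval -0.08 to 0.11). Of 7 other kidney cell type lists, 4 lay above them, where the account called for all 7. Peaks called in a single replicate could not enter this test, and windows with many such peaks of replicate 1 held the proximal tubule genes Fbp1 and Pck1. The test therefore cannot decide on this account. Differences in nuclei, digestion or library preparation, and differences between the tissue samples themselves, may contribute and stay open.

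Peaks called in replicate 1 with no partner in replicate 2, even at FDR 0.05, came in clusters. Of 13571 such peaks, 62 windows of 100 kb held at least 10, where shuffling gave 3.5, and they included windows at Hoxa5 to Hoxa13 (31 such peaks), Fbp1 and Fbp2 (28), Pou3f3 (15, with 28 in the next window), Tns1 (24) and Pax2 (17). Reads shared between near-identical copies were argued against as the main cause, since 12.6% (interval 10.6 to 14.9) of the 951 such peaks inside these windows lay in sequence with several copies, although this exceeds the 3.95% of other peaks of replicate 1 alone and the 1.17% of shared peaks, and 7 windows, such as that at Zfp988, consisted mostly of them. Peaks too weak for the shallower library were not told apart from a real difference. For the 831 of these peaks without several copies, the expected median height was 0.438. It lies at percentile 15.6 of the replicate 2 list used throughout, between the bounds set in advance. These peaks, however, were defined as absent from the replicate 2 list at FDR 0.05, whose lowest quartile of heights ends at 0.330. The bounds thus came from a list other than the one that defines these peaks, so the test cannot decide on this account. Replicate 2 had 14232 such peaks and 9 windows, among them Ndrg1 (16) and Timp3 (13), where shuffling gave 0.1.

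The X chromosome's peak density, at 0.365 of the autosomal one, was lower than each of 3 simple accounts would give. Halving autosomal heights, as for 1 copy, and dropping the weakest left a density of 0.762 of the full autosomal one. The observed X to autosome ratio over the same height cut was 0.307. At matched heights, with autosomal peaks held to 2 times the height, the ratio was 0.417. All peaks, in repeats or not, divided by the Mb outside repeats gave a ratio of 0.456. Protein-coding genes per Mb had a ratio of 0.670. These values argue against each account alone as the whole cause, while a combination of them may account for more of the gap and was not tested.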
